A study of Mus musculus with 22 samples.

How the data were processed

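The series holds 22 RNA-seq libraries in 11 groups of 2, made from mouse primary tumour cell lines. Per the labels, the tumour carried Lgr5CreER, a p53 deletion and a Rosa26-YFP reporter, and Pitx1, Klf5, Nfatc1 or Creb3l1 was knocked out with CRISPR/Cas9. Living single mCherry+ YFP+ tumour cells were sorted by FACS as EPCAM+ or EPCAM-, at day 8 for all 5 lines and at day 0 for EPCAM+ control cells only. The labels name no treatment that starts at day 0. They also do not say whether the 2 libraries of a group came from separate cultures or separate knockout clones, so every p-value here measures the spread between these samples only.

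The labels name the RNeasy micro kit, Ovation Solo RNA-seq libraries and paired-end sequencing on a NovaSeq. FastQC, Trimmomatic, STAR, Picard and HTSeq are named with the GRCm38/mm10 genome, without versions. All reads used here are the deposited values, and nothing was realigned.

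The deposited per-gene values were read as a score whose unit the labels do not state in full. They covered 49671 genes, of which 31139 were above 0 in at least 1 library. Deposited totals were 20007331 to 20014236 per library, and within a library the values fell on multiples of a fixed step, rounded up. That step, taken as 1 read, was 2.02 to 3.30 units. Dividing by it gave 6054918 to 9882692 reads in genes per library (median 7804821), and 99.8 to 99.9% of the values above 0 in a library were exactly a whole number of steps rounded up to the next unit. The step was estimated from the same values, but a step over 2 leaves more than 1 in 2 whole numbers unmatched. The values were therefore taken as read counts scaled to 1 common total, and were not scaled again. Libraries detected 20184 to 22616 genes (median 21546). Mitochondrially encoded genes held 1.56 to 2.84% of a library, and the 10 highest genes 6.92 to 11.0%.

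Gene identifiers were matched to GENCODE M21 on GRCm38, which held 49326 of them (99.3%). Positions and biotypes came from that annotation. A symbol shared by more than 1 identifier occurred 101 times, and each identifier was tested on its own.

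Genes with a value of at least 10 in at least 2 libraries were tested, 19569 genes; a value of 10 stood for 3 to 4 reads. The test was a linear model on log2(value + 1) over all 22 libraries with 1 mean per group, using limma 3.58.1 in R 4.3.3 with the data.table package (version 1.17.8). Variances were moderated with a trend on mean expression and a robust prior (11 residual degrees of freedom, median prior degrees of freedom 5.6). There were 19 contrasts, and p-values were adjusted by Benjamini-Hochberg within each. A gene counted as called at an adjusted p below 0.05, and rose or fell by the sign of its log2 fold change. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the values and drew the figures.

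The replicate number matches a batch tag in the labels, so samples with the same number were checked for pairing. The replicate difference (replicate 1 minus replicate 2) was correlated across genes between groups. Of 55 pairs of groups, 36 had a correlation over 0.1, with a median of 0.146 and a range of -0.131 to 0.381. Between the fractions of a line the correlation was 0.171 to 0.381 in all 5 lines. A second fit therefore carried the replicate number as a block common to all lines (10 residual degrees of freedom) and is printed as the blocked value. A pairing of the 2 fractions within a line was modelled in neither fit. The tests between fractions and the interactions therefore leave it out. The design is balanced, so blocked fold changes are the same and only the p-values differ.

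Fold changes without "log2" are ratios of group means in deposited units. Where a group was at 0 in both libraries the ratio is given as at least N-fold, with 3 reads per library (6.07 to 9.91 units) in place of 0. Where a group held only 1 to 3 reads the values are given without a ratio.

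Gene lists were written from general knowledge, 29 lists with 710 members, and tested with camera in limma at the preset correlation of 0.01, adjusted over the 29 lists of a contrast. Beside it stand the adjusted p with the correlation estimated from the data, and the number of members called when p-values are adjusted over the list alone. Named genes followed a rule fixed before the values were seen. It takes the 4 targeted genes and Epcam everywhere. It adds up to 10 called rises and falls per contrast by log2 fold change, with a mean of at least 50 in the higher group and both libraries apart, without predicted genes, mitochondrial genes and pseudogenes. It adds up to 4 called members of each called list.

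Similarity between knockouts was measured as the correlation of fold changes across genes. Because all knockouts share the control libraries, it was set against 100 simulations of unchanged groups with the same shared controls. For positions, the median log2 fold change of each chromosome was taken over 11101 genes with a mean of at least 100, against 999 random gene sets of the same size. TMM scaling, used only as an alternative, was written for this work (30% of M values and 5% of A values trimmed at each end).

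The pipeline was run on simulated negative binomial reads with known changes. With 50 changed genes at each size, it recovered 46% at 2-fold, 84% at 4-fold, 86% at 8-fold and 98% at 16-fold. It called 11 of 18456 unchanged genes in that contrast and 1 gene in a contrast without any change. A list raised 2-fold had a camera p of 4.73e-26 against 0.425 or more for 2 lists of unchanged genes, and a chromosome shift of 0.3 came back as 0.29. The genes changed by 2-fold or more had a mean of at least 50. Each gene was drawn on its own, without batches or correlation between genes. The simulation therefore does not check list calls or false calls where genes move together.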

Results

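Tumour cells of the control line and of 4 knockout lines were compared between EPCAM+ and EPCAM- fractions and against the control line. Between the fractions 23 genes fell in all 5 lines, and 0 genes were called in opposite directions. With only the compared groups in the fit no gene was called in all 5 lines. Of the knockouts, Pitx1 had the most called genes against the control line (80 in EPCAM+ and 179 in EPCAM- cells), followed by Creb3l1 (38 and 51) and Klf5 (10 and 30), and Nfatc1 had none. That order turned with only the compared groups in the fit (Pitx1 2 and 11, Creb3l1 7 and 33), and without control EPCAM+ replicate 2 Klf5 had 46 in EPCAM+ cells against 33 in Creb3l1. Each group held 2 libraries, so the counts moved with single libraries, and the values are printed where they did.

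The targeted genes differed in how far their own mRNA reported the knockout. Pitx1 fell 3.16-fold in Pitx1 knockout EPCAM+ cells (1473 and 1627 against 5432 and 4358, log2 -1.65, standard error 0.20, adjusted p 0.000731). In EPCAM- cells it fell 4.34-fold (1205 and 1585 against 6438 and 5668, log2 -2.13, adjusted p 5.52e-05). Nfatc1 was 3.47-fold lower in its knockout in EPCAM+ cells (194 and 182 against 817 and 488, log2 -1.74, adjusted p 0.315), which passed only in the blocked fit (0.00065). In EPCAM- cells it was 3.48-fold lower (249 and 189 against 981 and 542, log2 -1.74, adjusted p 0.290, blocked 0.000644). Klf5 mRNA was near the control level in the Klf5 knockout (2247 and 1961 against 2585 and 1733, log2 -0.01, adjusted p 1; in EPCAM- 2008 and 2182 against 2941 and 1803, log2 -0.14, adjusted p 1). A small CRISPR edit can leave mRNA levels as they were, so the mRNA does not check this knockout. Creb3l1 was at 0 to 12 in every library except those of the control EPCAM- group (137 and 26), against 6 and 0 in Creb3l1 knockout EPCAM- cells (log2 -4.53, adjusted p 0.212, blocked 0.0583). EPCAM- cells of the other knockouts were also near 0 (8 and 3 in Pitx1, 8 and 5 in Klf5, 0 and 0 in Nfatc1). The mRNA therefore does not check this knockout either.

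**Figure D1:**
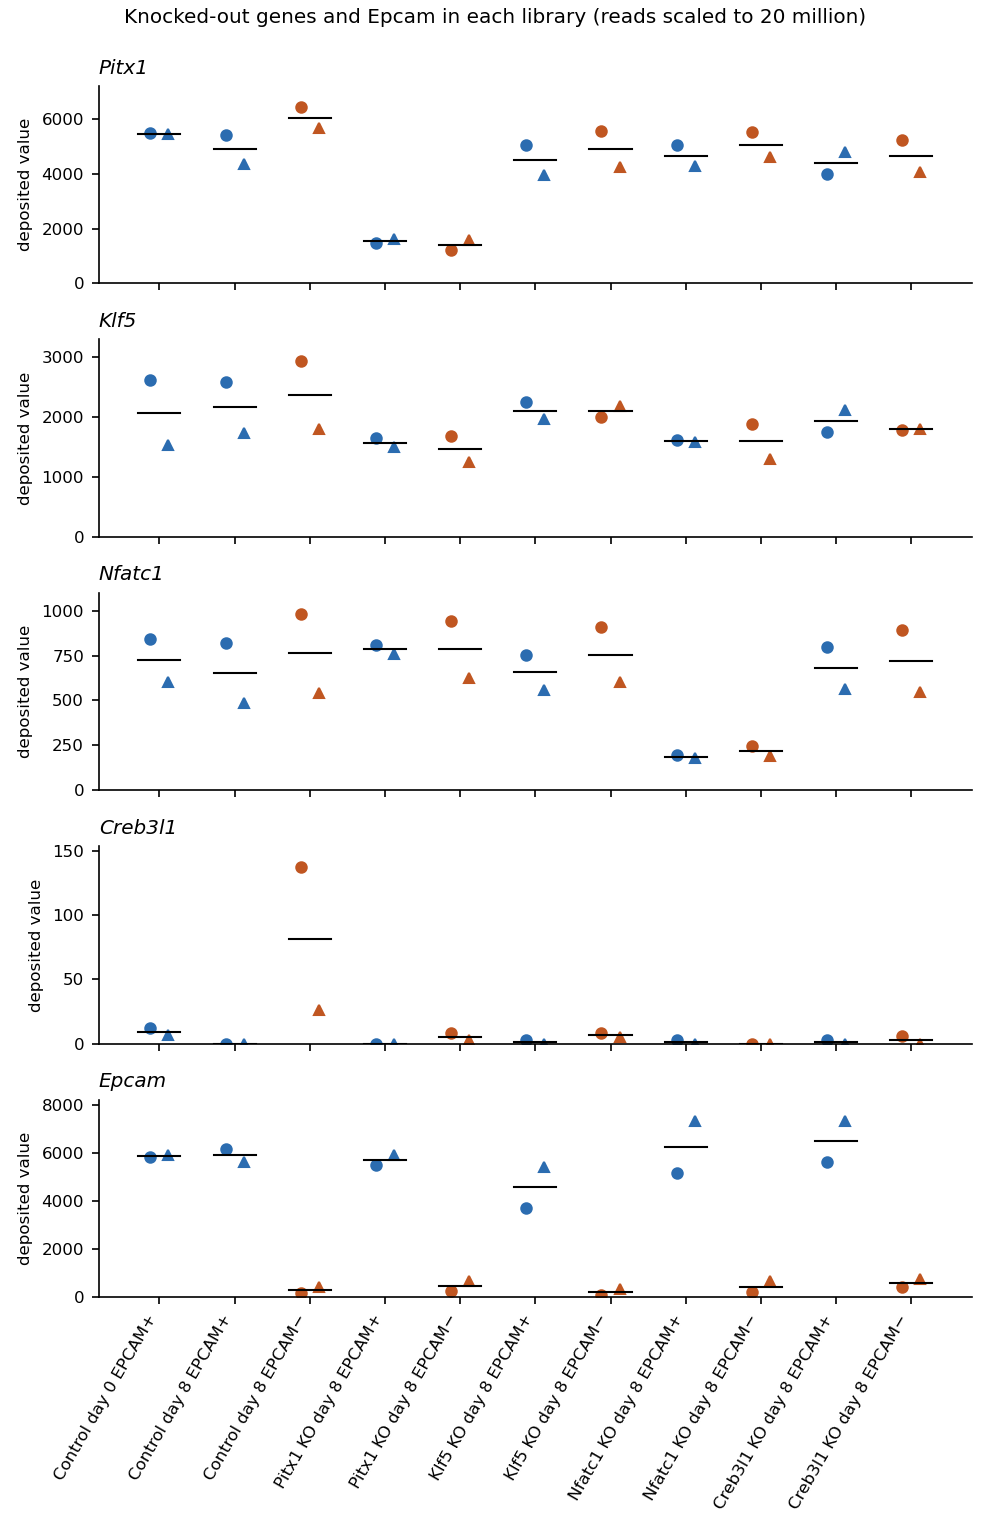
Deposited value of Pitx1, Klf5, Nfatc1, Creb3l1 and Epcam in each library, 1 panel per gene. Circles are replicate 1, triangles replicate 2; blue is EPCAM+, orange is EPCAM-, and the black line is the group mean (n = 2 libraries).

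In the control line at day 8, EPCAM- cells had lost most of the epithelial junction transcripts and carried more Vim than EPCAM+ cells. Epcam, the sorted marker, fell (180 and 441 against 6153 and 5633, log2 -4.38, standard error 0.63, adjusted p 0.00361). The epithelial transcription and splicing regulators Ovol1, Grhl2 and Esrp1 fell 10.9-fold, 7.09-fold and 4.67-fold, and Ovol2 fell at least 7.65-fold (0 and 0 against 71 and 47). The junction and trafficking genes Rab25 and Mal2 fell 33.9-fold and 30.1-fold, and Crb3 fell (0 and 3 against 134 and 68, log2 -5.59). Lama3, a laminin chain of the basement membrane, fell 10.8-fold, Lypd3 5.80-fold and Krt18 2.11-fold. Vim rose 5.94-fold (67534 and 49071 against 9875 and 9745, log2 2.55, adjusted p 0.0194) and Acta2, the smooth muscle actin, 13.8-fold (log2 3.95, adjusted p 0.0376, lost with voom at 0.162).

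In that comparison 126 genes were called, 16 rose and 110 fell (blocked 224, 58 and 166). Other rises were Gprin3 (35.4-fold, log2 4.92), Fat4 (10.6-fold), Olfml3 (8.50-fold), Ttc28 (7.55-fold), Lix1l (4.15-fold) and Rgl1 (3.19-fold). Creb3l1 rose (137 and 26 against 0 and 0, log2 5.93, adjusted p 0.0228), which is the only place where this targeted gene was above 12 units. Other falls were Prom2 (59.4-fold), Gpx2 (25.3-fold, lost in the blocked fit at 0.0546), Trp53i11 (24.8-fold), Atp8b1 (at least 6.55-fold) and Hpca (0 and 3 against 81 and 71). The Klra genes Klra9 (at least 16.5-fold), Klra3 (at least 7.07-fold) and Klra8 (6 and 0 against 303 and 109) also fell; they are close paralogs, so which copy the reads came from is uncertain. The count was 14 with only the compared groups in the fit, 32 without control EPCAM+ replicate 1, 177 (68 rose and 109 fell) without its replicate 2, and 57 without control EPCAM- replicate 1 (6 rose and 99 fell without its replicate 2); a group left with a single library is taken to vary like the other groups. Of 29 named calls, 6 held with each library left out (Crb3, Esrp1, Klra9, Lama3, Lypd3 and Ovol2). Atp8b1 (0.0886), Creb3l1 (0.0601), Fat4 (0.108), Gpx2 (0.259), Klra3 (0.0640), Klra8 (0.219), Olfml3 (0.127), Prom2 (0.126), Rgl1 (0.0539) and Trp53i11 (0.0657) were lost with voom, adjusted p in brackets.

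Among the gene lists of this comparison, 19 of 36 epithelial junction genes fell and 17 were not called (23 fell when adjusted over the list alone, median log2 -2.03, adjusted p 1.5e-46, with estimated correlation 0.000178). Of 17 epithelial regulators, a list that holds Pitx1 and Klf5, 6 fell (8 alone, median -1.62, 4.1e-13, estimated 0.00118). Simple epithelial keratins also passed with the estimated correlation (1 of 4 fell, 4 alone; 6.5e-09, estimated 0.0245). The remaining list calls were lost with it. These were lower basal keratinocyte genes (1 of 19 fell, 2 alone; 1.99e-05, estimated p 0.119) and squamous differentiation genes (1 of 19 fell, 1 alone; 2.61e-05, estimated p 0.237). They were also higher EMT transcription factors (Creb3l1 alone of 16 rose, 4 over the list alone, 15 positive; 2.4e-08, estimated p 0.0575) and mesenchymal cytoskeleton genes (2 of 24 rose, 2 alone, 23 positive, median 0.81; 1.7e-08, estimated p 0.0575). Extracellular matrix genes were higher as a list (0 of 40 called, 4 rose alone, median 0.71; 1.85e-07, estimated p 0.119). Cholesterol biosynthesis genes were lower (0 of 24 called, 0 alone, median -0.42; 8.6e-07, estimated p 0.368). With 0 members called, matrix proteases (24 genes, median 0.42; 0.0258, estimated p 0.578) and antigen presentation genes (15 genes, median 0.30; 0.0185, estimated p 0.578) were higher. S and G2/M genes were lower (0 of 40 called, median -0.16; 0.0431, estimated p 0.796).

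Against the day 0 EPCAM+ control cells, 4 of 16 EMT transcription factors rose in the day 8 EPCAM- control cells, a list call that was lost with the estimated correlation (p 0.106). Zeb1 rose 12.6-fold (1183 and 654 against 121 and 25, log2 3.97, adjusted p 0.0362, voom 0.0616), Zeb2 7.40-fold (log2 3.01), Snai1 5.40-fold (log2 2.40, voom 0.0765) and Prrx1 1.76-fold (log2 0.82). Vim rose 8.94-fold and Wnt5a, a secreted Wnt ligand, 23.2-fold (voom 0.0779). Of 40 matrix genes 3 rose (list with estimated correlation p 0.329): Col1a2 at least 3.08-fold (40 and 14 against 0 and 0, voom 0.208), Vcan 2.56-fold and Lamc1 1.80-fold. The simple keratins Krt7, Krt19, Krt18 and Krt8 fell 12.1-fold, 5.72-fold, 2.09-fold and 1.77-fold, and 7 of 24 cholesterol biosynthesis genes fell (list with estimated correlation p 0.0748), among them Fdps 3.06-fold (voom 0.0574), Idi1 2.88-fold, Pmvk 2.87-fold and Hmgcs1 2.35-fold.

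This comparison joins the sort and the time, and 393 genes were called, 134 rose and 259 fell (blocked 843, 380 and 463). Further rises were Mef2c (at least 7.12-fold), Masp1 (at least 11.7-fold, 12 and 193 against 0 and 0), Robo2 (at least 6.89-fold), Fhl1 (14.2-fold), Dpysl3 (11.2-fold, blocked 0.0747) and Hoxb9 (9.47-fold). Fat4 rose too (60 and 88 against 3 and 4). Further falls were Klra9 (at least 21.3-fold), Klra8, Atp8b1 (at least 18.7-fold), Ppp2r2c (at least 13.2-fold), Crb3 (0 and 3 against 169 and 202), Ovol2 (at least 10.8-fold), S100a14 (43.0-fold), Fgfbp1 (76.5-fold), Prom2 (79.2-fold) and Cwh43 (at least 8.69-fold). The epithelial genes Epcam, Rab25, Mal2, Ap1m2, Ovol1, Grhl2, Esrp1, Lama3 and Lypd3 fell 18.9-fold, 60.9-fold, 51.9-fold, 28.4-fold, 11.2-fold, 8.11-fold, 4.90-fold, 4.94-fold and 5.86-fold. The count was 161 with only the compared groups, 304 (140 rose and 164 fell) and 98 without day 0 replicate 1 and 2, and 199 and 185 without replicate 1 and 2 of the EPCAM- group. Of 43 named calls, 13 held with each library left out, among them Epcam, Esrp1, Grhl2, Ovol2, Prom2 and Vim. Dpysl3 (0.0893), Fgfbp1 (0.119), Fhl1 (0.138), Klra8 (0.0612), Masp1 (0.196), Robo2 (0.0833) and S100a14 (0.113) were lost with voom.

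The epithelial lists passed with the estimated correlation here too: junction genes (21 of 36 fell, 27 alone, median -2.46, 3.9e-40, estimated 0.000359), regulators (6 of 17 fell, 9 alone; 1.0e-09, estimated 0.00464) and simple keratins (4 of 4 fell; 2.2e-08, estimated 0.0319). Called at the preset correlation and lost at the estimated one were 7 lists. Cholesterol biosynthesis genes were lower (7 of 24 fell, 20 alone, median -0.93, 1.4e-19, estimated p 0.0748), as were ribosomal protein genes (0 of 42 called, median -0.21, 1.36e-06, estimated p 0.594), mostly in replicate 2 (12.87 and 12.67 against 12.89 and 13.08). EMT transcription factors were higher (4 of 16 rose, 6 alone; 1.2e-06, estimated p 0.106), with mesenchymal cytoskeleton genes (Vim alone of 24 rose, 8 over the list alone; 2.2e-06, estimated p 0.117) and matrix genes (3 of 40 rose, 5 alone; 0.000306, estimated p 0.329). Basal keratinocyte genes (Lama3 alone of 19 fell; 0.0239, estimated p 0.467) and squamous genes (Lypd3 alone of 19 fell; 9.3e-05, estimated p 0.289) were lower. S and G2/M genes passed only in the blocked fit (0.165, blocked 0.0299).

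Between day 0 and day 8 within EPCAM+ control cells no gene was called. Without adjustment 831 genes had a p below 0.05, and the smallest adjusted p was 0.0659 for Nr4a2. That is fewer genes than the share of 0.05 of the 19569 tested genes expected without any difference. The blocked fit called 2 genes (Hes1 among them) and a voom fit on the recovered reads 0; the count was 3 without day 0 replicate 1 and 1 without day 8 replicate 2. Epcam was 6153 and 5633 at day 8 against 5816 and 5917 at day 0 (log2 0.01). Cholesterol biosynthesis genes were lower at day 8 as a list (23 of 24 negative, 0 called, median -0.62, 5.5e-16), and so were junction genes (0 of 36 called, median -0.31, 0.000493), ribosomal protein genes (0 of 42 called, median -0.16, 3.09e-06) and YAP-TEAD targets (0 of 22 called, median -0.24, 0.0435). All 4 list calls were lost with the estimated correlation (p 0.493, 0.547, 0.801 and 0.801). Replicate 2 carried most of the difference in cholesterol genes (9.79 and 9.72 against 10.05 and 10.72) and junction genes (10.04 and 9.48 against 10.15 and 10.19), and all of it in ribosomal protein genes (12.89 and 12.76 against 12.89 and 13.08). Unfolded protein genes passed only in the blocked fit (0.0738, blocked 0.0366).

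Epithelial genes were also lower in EPCAM- than in EPCAM+ cells of every knockout line. In all 5 lines 23 genes fell and 0 rose. With only the compared groups in the fit, Klf5 and Nfatc1 had 0 calls between fractions, so no gene was then called in all 5 lines. The falls, with the mean fitted log2 fold change over the 5 lines, included Cdh1 (-3.60), Epcam (-4.07), Mal2 (-4.70), Mal (-4.68), Serpinb5 (-4.02), Map7 (-3.93), Ocln (-3.65), Ovol1 (-3.55), Itgb6 (-3.54), Slc4a11 (-3.43), Erbb3 (-3.31), Galnt3 (-3.19), Myo5b (-3.09), Marveld2, Cnksr1, Epn3, Lypd3, Rbm47, Morc4, Arap2, Mpzl3 and Prrg4. In at least 1 line 129 genes fell and 30 rose, and 0 genes were called in opposite directions. Of the 126 genes called in the control line, 125 had the same sign in the Pitx1 knockout, 124 in Klf5, 125 in Nfatc1 and 125 in Creb3l1. The median ratio of the knockout to the control fold change over these genes was 0.763, 0.790, 0.852 and 0.795, and choosing the genes in the control line pulls that ratio below 1. Across all genes the fraction fold changes of a knockout and the control correlated at 0.384 to 0.455. Vim rose 6.56-fold in the Nfatc1 knockout (log2 2.73) and 5.93-fold in the Creb3l1 knockout (log2 2.57).

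Each knockout was also tested for a fraction difference that departed from the control line, and 0 genes were called in any of the 4 interactions. Unadjusted p-values below 0.05 were found for 365 genes in Pitx1, 268 in Klf5, 374 in Nfatc1 and 222 in Creb3l1, and the blocked and voom fits called 0 in each. Without any difference a share of 0.05 of the 19569 tested genes would be found there. That is more than each of these counts, so they are no sign of a difference. Counts so far under that share also make it a poor yardstick for this test. The median standard error was 0.551, and the pairing of the fractions within a line was left out. The 0 calls therefore do not show that the fraction differences were equal. Falls shared with the control line numbered 48 in Pitx1, 53 in Klf5, 65 in Nfatc1 and 47 in Creb3l1, where 0.304, 0.315, 0.405 and 0.304 would be shared if the calls were independent.

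In the Pitx1 knockout 62 genes differed between fractions, 8 rose and 54 fell in EPCAM- (blocked 138, 23 and 115). Rises included Mcc (5.63-fold), Nrp1 (3.32-fold), Rab30 (2.97-fold), the growth factor Csf1 (2.70-fold), Pcdh18 (2.44-fold) and Syde1 (2.21-fold). Falls included Mal (35.4-fold), Serpinb5 (23.1-fold), Crb3 (22.6-fold), Ppp2r2c (20.8-fold), Cdh1 (15.6-fold; 130 and 151 against 2339 and 2030), Erbb3 (15.4-fold), Ocln (15.1-fold), Ovol1 (14.3-fold), Epcam (12.3-fold), Lama3 (10.1-fold) and Lypd3 (3.44-fold). Mal2 (5 and 0 against 173 and 94), Prom2 (0 and 8 against 90 and 101) and Klra9 (at least 9.26-fold) fell as well. The count was 8 with only the compared groups, 24 and 39 (0 and 14 rose) without EPCAM+ replicate 1 and 2, and 19 and 56 without EPCAM- replicate 1 and 2; 6 of 21 named calls held with each library left out (Cdh1, Erbb3, Klra9, Mal2, Ocln and Serpinb5). Klra9 (0.118), Mal2 (0.203), Nrp1 (0.289), Prom2 (0.606), Rab30 (0.0505) and Syde1 (0.0544) were lost with voom.

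In the Klf5 knockout 56 genes were called between fractions, all of which fell (blocked 102, 4 rose and 98 fell). They included Mal (37.3-fold), Rab25 (34.8-fold), Mal2 (23.9-fold), Epcam (21.4-fold; 90 and 336 against 3702 and 5408), Mpzl2 (18.7-fold), Map7 (18.1-fold), Ovol1 (13.3-fold), Serpinb5 (13.1-fold) and Lama3 (7.40-fold). Prom2 fell at least 7.26-fold, Ovol2 at least 4.61-fold, and Crb3 fell from 75 and 72 to 3 and 0. The count was 0 with only the compared groups, 14 and 5 without EPCAM+ replicate 1 and 2, and 16 and 38 without EPCAM- replicate 1 and 2; of 13 named calls only Serpinb5 held with each library left out. Crb3 (0.0570), Mal (0.566), Mal2 (0.143), Prom2 (1) and Rab25 (0.143) were lost with voom.

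In the Nfatc1 knockout 84 genes were called between fractions, 12 rose and 72 fell (blocked 187, 48 and 139). Besides Vim, Gprin3 (87 and 132 against 3 and 4), Evi2a (70 and 33 against 0 and 7), Pdzrn3 (11.6-fold, blocked 0.0539), Lix1l (3.29-fold), Gchfr (2.29-fold) and Pcdh18 (1.88-fold) rose. Falls included Mal (17.0-fold), Itgb6, an integrin subunit of epithelia (16.7-fold), Serpinb5 (15.0-fold), Cdh1 (14.4-fold), Epcam (14.1-fold), Ovol1 (8.75-fold), Lama3 (6.21-fold), Lypd3 (5.90-fold) and Grhl2 (4.77-fold). Atp8b1 fell at least 8.88-fold and Fut1 at least 6.68-fold, and Ap1m2 (3 and 3 against 144 and 149), Ovol2, Ppp2r2c and Crb3 fell to a few reads. The count was 0 with only the compared groups, 45 and 52 (20 rose in each) without EPCAM+ replicate 1 and 2, and 16 and 49 (0 rose) without EPCAM- replicate 1 and 2; 6 of 23 named calls held with each library left out (Ap1m2, Cdh1, Itgb6, Lypd3, Ovol2 and Serpinb5). Ap1m2 (0.0571), Atp8b1 (0.0716), Crb3 (0.0602), Evi2a (0.180), Fut1 (0.0614), Gprin3 (0.208), Lix1l (0.0507), Ovol1 (0.0507), Pcdh18 (0.0508), Pdzrn3 (0.380) and Ppp2r2c (0.0515) were lost with voom.

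In the Creb3l1 knockout 57 genes were called between fractions, 3 rose and 54 fell (blocked 114, 13 and 101). Vim (30486 and 36078 against 6060 and 5163) and the chemokine Ccl9 (44 and 79 against 5 and 0) rose. Falls included Prom2 (30.4-fold), Mal (18.5-fold), Ovol1 (12.6-fold), Map7 (26 and 20 against 225 and 326), Ocln (11.9-fold), Srcin1 (11.9-fold), Epcam (11.1-fold), Serpinb5 (11.1-fold), Cdh1 (8.36-fold), Lypd3 (5.46-fold) and Grhl2 (5.32-fold). Ovol2 fell at least 7.15-fold and Mal2 fell from 158 and 136 to 3 and 5. The count was 23 with only the compared groups, 14 and 6 without EPCAM+ replicate 1 and 2, and 7 and 29 without EPCAM- replicate 1 and 2; Cdh1 and Serpinb5, of 16 named calls, held with each library left out. Mal2 (0.186), Prom2 (0.442) and Srcin1 (0.0648) were lost with voom.

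The epithelial lists passed in all 4 knockouts with the estimated correlation. Junction genes fell in number 10, 10, 14 and 9 of 36 in Pitx1, Klf5, Nfatc1 and Creb3l1 (24, 23, 23 and 22 over the list alone; estimated p 0.000375, 0.000112, 0.000173 and 0.000169). Of 17 epithelial regulators 2, 3, 5 and 4 fell (7, 6, 7 and 6 alone; estimated p 0.00159, 0.000525, 0.00116 and 0.000385). The matrix list was higher at the preset correlation in all 4 with 0 of 40 called (3.2e-08, 1.9e-06, 0.00136 and 0.000429) and was lost with the estimated one (p 0.149, 0.198, 0.430 and 0.501). The mesenchymal list was higher with 0, 0, 1 and 1 of 24 called (0.000306, 6.6e-07, 0.000119 and 7.3e-07) and was lost as well (p 0.278, 0.123, 0.302 and 0.1004).

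**Figure D2:**
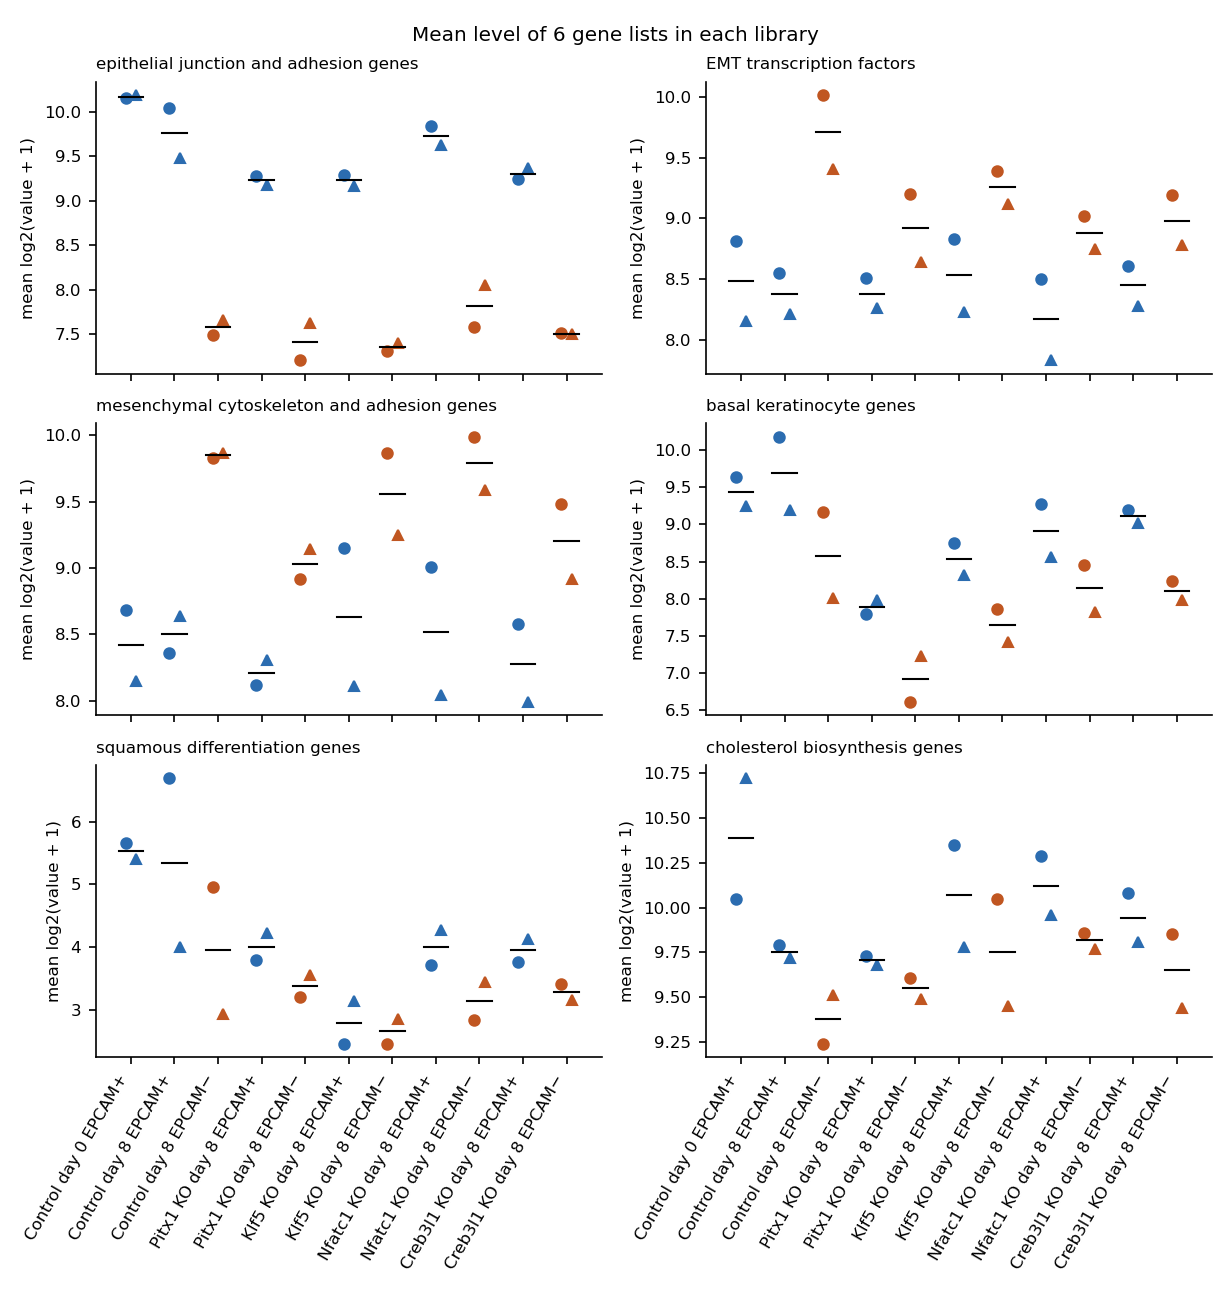
Mean log2(value + 1) of the members of 6 gene lists in each library. Circles are replicate 1, triangles replicate 2; blue is EPCAM+, orange is EPCAM-. The junction list was at 9.17 to 10.19 in EPCAM+ libraries and at 7.21 to 8.06 in EPCAM- libraries.

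Krt17 fell in both fractions of the Pitx1 knockout. In EPCAM+ cells it fell 71.3-fold (72 and 38 against 4365 and 3481, log2 -6.19, standard error 0.63, adjusted p 0.000466), and in EPCAM- cells 134-fold (8 and 37 against 2175 and 3846, log2 -7.29, adjusted p 5.67e-05). Krt14 fell 52.7-fold in EPCAM- cells (log2 -5.58, adjusted p 0.0142, lost with voom at 0.141); Krt14 and Krt17 are close paralogs, so their single values carry some doubt. The basal adhesion genes Itga6 (9.10-fold in EPCAM-, log2 -3.10) and Cdh3 (3.19-fold in EPCAM+, 2.54-fold in EPCAM-, the latter lost with voom at 0.0727) fell as well. The tight junction gene Cldn3 fell in EPCAM+ cells (3 and 0 against 58 and 331, log2 -6.13) and at least 23.9-fold in EPCAM- cells, both lost with voom (0.290 and 0.173).

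In EPCAM+ cells 80 genes were called in the Pitx1 knockout, 26 rose and 54 fell (blocked 386, 195 and 191). Falls included Lrch2 (at least 18.7-fold), the transcription factor Gata4 (at least 7.40-fold, 0 and 0 against 63 and 55), Crmp1 (3 and 0 against 126 and 607, log2 -7.12), Cldn2 (log2 -5.64), Adgrl2 (log2 -5.62), Lrig3 (log2 -5.32), Epdr1 (log2 -5.03) and Egln3 (log2 -4.96), the last 6 down to a few reads. The control values of Lrch2 were 14 and 285, so its bound rests on control replicate 2. Rises were Anp32a (6.30-fold), Apc2 (3.23-fold), Mxi1 (2.91-fold), Atg13 (2.49-fold), Stard13 (2.41-fold), Rilpl1 (2.36-fold), Slc39a13 (2.34-fold), Ttc7b (2.03-fold), Ndufs3 (1.98-fold) and Arfgap2 (1.95-fold). Of these, Atg13, Slc39a13, Ndufs3 and Arfgap2 lie on chromosome 2, Mxi1 on chromosome 19 and Ttc7b on chromosome 12, in segments whose genes shifted together and are described further on. The count was 2 with only the compared groups and 39 with voom; it was 31 without control replicate 1, 80 without control replicate 2 (48 rose and 32 fell, 33 of them shared with the full fit), 23 without Pitx1 knockout replicate 1 and 50 without replicate 2. Of 22 named calls, 7 held with each library left out (Adgrl2, Cldn2, Crmp1, Egln3, Gata4, Krt17 and Pitx1). Apc2 (0.0564), Atg13 (0.0569), Cldn2 (0.180), Crmp1 (0.263), Egln3 (0.0685), Lrch2 (0.490), Lrig3 (0.307), Ndufs3 (0.0633) and Ttc7b (0.0564) were lost with voom.

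In EPCAM- cells 179 genes were called in the Pitx1 knockout, 66 rose and 113 fell (blocked 491, 230 and 261). Falls included Sostdc1 (at least 124-fold, 0 and 0 against 1801 and 67), the glypican Gpc4 (at least 45.7-fold), Gpr149 (at least 24.5-fold), Cdh11 (0 and 3 against 357 and 340), Crmp1, Lrch2, Lrig3 (0 and 3 against 160 and 381) and Ptprz1 (5 and 0 against 169 and 159). Sostdc1, Gpc4, Gpr149, Cdh11, Lrch2, Ptprz1 and Cldn3 were lower by more than 2 log2 units in all 4 knockouts, which share the control libraries. Rises were Tmprss11e (17.1-fold), Srgap1 (4.52-fold), Cnih2 (4.49-fold), Harbi1 (3.96-fold), Sh3bp2 (3.60-fold), Bst1 (3.57-fold), Rhof (3.44-fold), Plscr2 (3.19-fold), Pacsin3 (3.02-fold) and Stard13 (2.81-fold); Harbi1 and Pacsin3 lie in the chromosome 2 segment and Cnih2 on chromosome 19. The count was 11 with only the compared groups, 28 without control replicate 1, 182 (100 rose and 82 fell) without control replicate 2, and 54 and 56 without Pitx1 knockout replicate 1 and 2. Of 25 named calls, 8 held with each library left out (Cldn3, Crmp1, Gpc4, Krt17, Lrig3, Plscr2, Stard13 and Pitx1). Crmp1 (0.152), Gpc4 (0.128), Lrch2 (0.223), Lrig3 (0.0775), Sostdc1 (0.418), Srgap1 (0.0782) and Tmprss11e (0.193) were lost with voom.

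The basal keratinocyte list was lower in both fractions of the Pitx1 knockout: 2 of 19 fell in EPCAM+ cells (5 alone, median -0.82, 5.4e-08) and 4 of 19 in EPCAM- cells (5 alone, median -1.26, 7.5e-09). Both list calls were lost with the estimated correlation (p 0.165 and 0.121), and the difference was larger in replicate 1 (7.79 and 7.98 against 10.18 and 9.19 in EPCAM+, 6.61 and 7.23 against 9.16 and 8.01 in EPCAM-). In EPCAM+ cells, junction genes (Cldn3 and Cdh3 of 36 fell; 0.0379, estimated p 0.781) and ribosomal protein genes (0 of 42 called, median -0.14, 0.00734, estimated p 0.989) were lower. In EPCAM- cells, EMT transcription factors, a list that holds Creb3l1 and Nfatc1, were lower (0 of 16 called, 4 fell alone, median -0.23, 0.00645, estimated p 0.981). So were antigen presentation genes (Erap1, 1.86-fold, alone of 15 fell and 2 over the list alone, median -0.41, 0.00680, estimated p 0.981). Erap1 lies on chromosome 13.

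Whole chromosomes and a segment of chromosome 2 were shifted in the Pitx1 knockout. The median log2 fold change of chromosome 12 was 0.31 in EPCAM+ and 0.36 in EPCAM- cells, of chromosome 13 -0.30 and -0.34, and of chromosome 19 0.20 and 0.33. Chromosome 5 was at 0.22 and 0.19, and chromosome 17 at -0.05 and -0.22. These shifts were not all particular to this line. Chromosome 19 was at 0.16 and 0.25 in the Creb3l1 knockout, and chromosome 13 at -0.14 and -0.10 in Nfatc1 and -0.10 in both fractions of Klf5. Chromosome 17 was at -0.16 in EPCAM+ cells of Nfatc1, a larger shift than in EPCAM+ cells of Pitx1 (-0.05) but not than in EPCAM- cells (-0.22). Chromosome 12 was at 0.11 in EPCAM- cells of Nfatc1 and Creb3l1. In a segment of chromosome 2 that starts at 84 Mb it was 0.64 and 0.72 (72 genes). That segment held 8 of the 26 rises in EPCAM+ cells (0.174 expected, Fisher p 4.59e-12) and 22 of the 66 in EPCAM- cells (0.442 expected, Fisher p 3.29e-32). Chromosome 13, which carries Pitx1, held 11 of 54 falls (1.93 expected, Fisher p 2.71e-06) and 18 of 113 (4.05 expected, Fisher p 1.06e-07). Chromosome 12 held 1 of the 26 rises (0.822 expected, Fisher p 0.567) and 7 of the 66 (2.09 expected, Fisher p 0.00474). Chromosome 19 held 1 (0.763 expected, Fisher p 0.539) and 3 (1.94 expected, Fisher p 0.445), which is no clear excess. The 4 segments together held 10.3% of the tested genes, with 10 of 26 rises and 13 of 54 falls in EPCAM+ cells and 32 of 66 rises and 22 of 113 falls in EPCAM- cells. With the genes of these segments taken out and the p-values of the same fit adjusted again, 52 and 103 genes were called. The chromosome 2 window was chosen after looking at the values, and chromosomes 12, 13 and 19 by their medians in these same contrasts. An excess of calls in the direction of the shift follows in part from that choice, so the Fisher p-values are no independent support. The chromosome 13 falls include Pitx1 itself, and Epdr1 and Emb, which also fell in the Creb3l1 knockout.

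**Figure D3:**
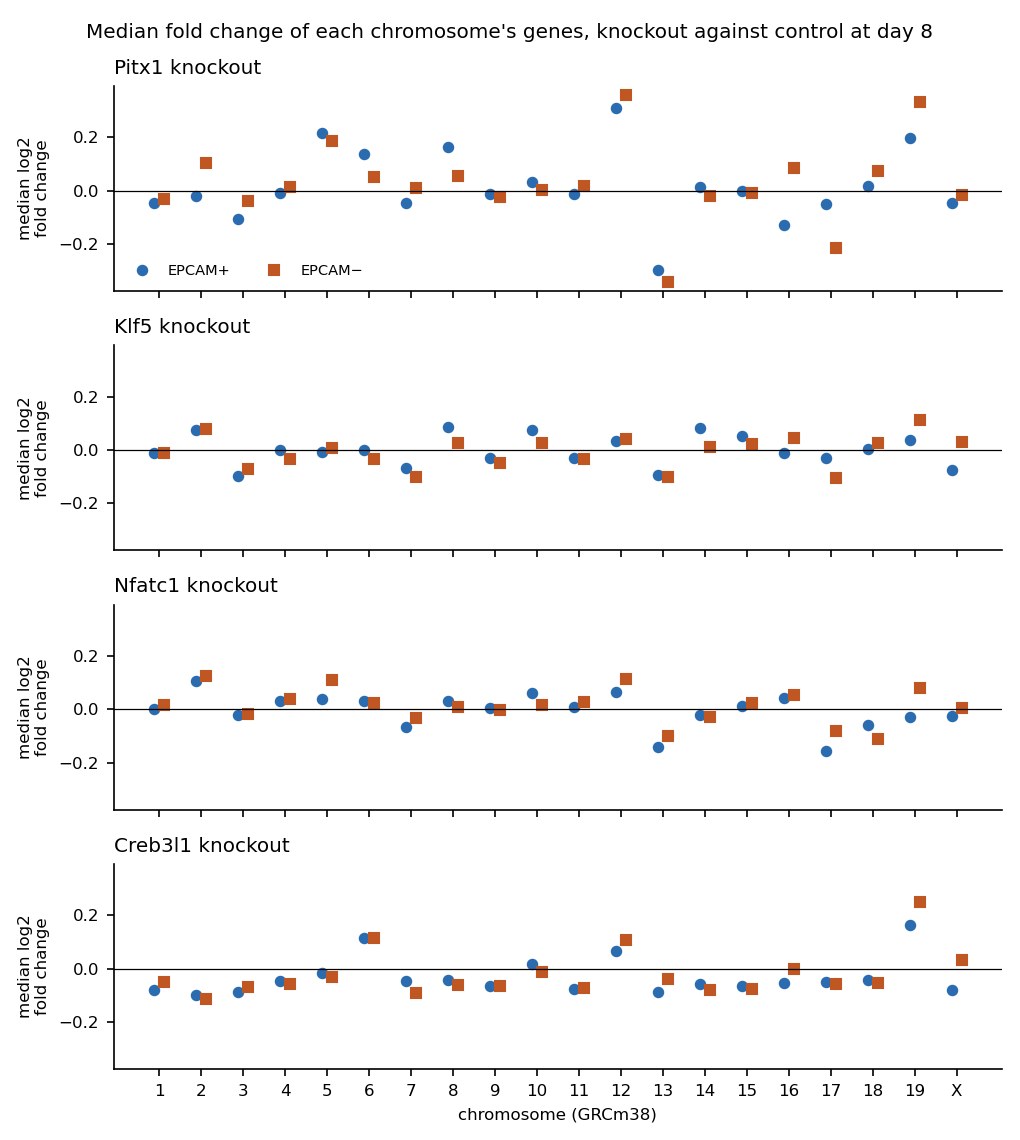
Median log2 fold change against the control line of the genes of each chromosome, 1 panel per knockout. Blue circles are EPCAM+, orange squares EPCAM- (n = 2 libraries per group).

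In the Klf5 knockout 10 of 10 and 27 of 30 called genes fell, but without control replicate 2 the calls were 18 rises and 28 falls in EPCAM+ cells and 32 rises and 41 falls in EPCAM- cells. Hoxb9 fell 20.5-fold in EPCAM+ cells (18 and 9 against 131 and 423) and 110.0-fold in EPCAM- cells (3 and 10 against 590 and 840, log2 -6.73, adjusted p 0.000301), and Hoxb8 at least 10.1-fold in EPCAM- cells. Hoxb9 was also called lower in both fractions of the Creb3l1 knockout, which shares the control libraries. Wnt7a, a Wnt ligand, fell 5.58-fold and 12.2-fold. The homeobox gene Lmx1a fell at least 15.3-fold in EPCAM+ cells (0 and 0 against 144 and 95, adjusted p 0.00315). The kallikrein Klk10 fell 65.4-fold and 102-fold, with control values of 2861 and 672 in EPCAM+ and 2326 and 218 in EPCAM-, and was lost in the blocked fit (0.0925 and 0.0589) and with voom (0.703 and 0.767). Itga6 fell 13.1-fold in EPCAM- cells (562 and 573 against 11125 and 3738).

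In EPCAM+ cells 10 genes fell and 0 rose in the Klf5 knockout (blocked 27, 2 rose and 25 fell). Other falls were Map6 (4.39-fold, 229 and 240 against 1039 and 1021, adjusted p 0.00102), Gprc5b (4.67-fold), Oaf (2.97-fold) and Sgk3 (2.87-fold). Oaf was also called lower in both fractions of the Pitx1 knockout, with the smallest adjusted p of its EPCAM+ comparison with the control (0.000212). The count was 0 with only the compared groups and 5 with voom; it was 2 and 46 without control replicate 1 and 2, and 1 without either knockout replicate. Only Map6, of 8 named calls, held with each library left out. Hoxb9 (0.415) and Lmx1a (0.441) were lost with voom. In EPCAM- cells 30 genes were called, 3 rose and 27 fell (blocked 59, 10 and 49). Sostdc1 (at least 130.4-fold, 0 and 0 against 1801 and 67, so the bound rests on control replicate 1), Msln (17.5-fold), Xpnpep2 (at least 15.2-fold), Tph1 (at least 9.43-fold) and Hoxa9 (3 and 3 against 69 and 37) fell, and Plscr2 rose 2.69-fold. Sostdc1 was lower in all 4 knockouts. The count was 0 with only the compared groups and 11 with voom; it was 6 and 73 without control replicate 1 and 2, and 11 and 12 without knockout replicate 1 and 2. Hoxb8, Hoxb9 and Wnt7a, of 11 named calls, held with each library left out. Hoxa9 (0.0537), Itga6 (0.0537), Msln (0.0714), Sostdc1 (0.864), Tph1 (0.0537), Wnt7a (0.0537) and Xpnpep2 (0.628) were lost with voom.

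Every list call of the Klf5 knockout was lost with the estimated correlation. In EPCAM+ cells the squamous list was lowest (Klk10 alone of 19 fell, 6 over the list alone, median -2.33, 1.12e-08, estimated p 0.441). With 0 members called, junction genes (median -0.24, 0.0112), basal keratinocyte genes (2 of 19 fell alone, median -0.66, 0.00593), S and G2/M genes (median -0.28, 0.00593) and ribosomal protein genes (median -0.13, 0.00098) were lower. Cholesterol genes (median 0.40, 0.00227), matrix proteases (2 of 24 rose alone, median 0.30, 0.0200), AP-1 genes (median 0.57, 0.0200) and dissociation stress genes (median 0.44, 0.0312) were higher, all with estimated p 0.673 or 0.675. In all 9 lists the difference was larger in replicate 1: the mean level was 2.46 and 3.15 against 6.69 and 4.00 for squamous genes, 8.21 and 7.97 against 7.12 and 7.72 for matrix proteases, 10.21 and 9.44 against 9.53 and 9.31 for AP-1 genes, 10.80 and 9.86 against 10.05 and 9.64 for stress genes, and 10.35 and 9.78 against 9.79 and 9.72 for cholesterol genes. S and G2/M genes were at 10.93 and 11.66 against 11.57 and 11.58, so replicate 2 was not lower. Inflammatory genes passed only in the blocked fit (0.0872, blocked 0.0489). In EPCAM- cells basal keratinocyte genes (Itga6 alone of 19 fell; median -0.27, 0.0127) and squamous genes (Klk10 alone of 19 fell; median -1.20, 0.0127) were lower. Simple keratins (0 of 4 called, 3 rose alone, median 0.51, 0.00117) and cholesterol genes (0 of 24 called, median 0.35, 1.6e-05) were higher, all 4 with estimated p 0.737. AP-1 (median 0.48) and inflammatory genes (median 0.22; both 0.0339, estimated p 0.737) and dissociation stress genes (median 0.23, 0.0339, estimated p 0.857) were higher with 0 called, and ribosomal protein genes lower (median -0.11, 0.0322, estimated p 0.857). Replicate 2 did not differ that way in AP-1 genes (10.11 and 9.35 against 9.58 and 9.38) or cholesterol genes (10.05 and 9.45 against 9.24 and 9.51), and the squamous difference lay in replicate 1 (2.46 and 2.86 against 4.96 and 2.94). Stress genes were at 10.70 and 9.86 against 10.19 and 9.65. S and G2/M genes passed only in the blocked fit (0.1204, blocked 0.0208).

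In the Nfatc1 knockout no gene was called in either fraction, and Nfatc1 itself was the single gene called in each blocked fit. In EPCAM+ cells 1467 genes had an unadjusted p below 0.05 and the smallest adjusted p was 0.138. In EPCAM- cells the numbers were 734 and 0.206. A share of 0.05 of the 19569 tested genes, expected without any difference, lies between 734 and 1467. The voom fit called 0 in both. The count was 3 and 2 without Nfatc1 knockout EPCAM+ replicate 1 and 2, and 10 without control EPCAM- replicate 2. The genes related to calcineurin and NFAT were near the control level as a list (median 0.04 in EPCAM+, adjusted p 0.696, and 0.15 in EPCAM-, adjusted p 0.748).

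The list tests of the Nfatc1 knockout called groups of genes with 0 members called each, and all were lost with the estimated correlation. In EPCAM+ cells interferon response genes were higher (20 of 24 positive; median 0.60, 0.00240), with cholesterol genes (median 0.38, 3.0e-05), TGF-beta response genes (median 0.25, 0.0452), AP-1 genes (median 0.62, 0.0285) and dissociation stress genes (median 0.33, 0.0285). Ribosomal protein genes (median -0.23, 3.4e-08), squamous genes (median -1.34, 0.0237), mitochondrially encoded genes (median -0.36, 0.0202) and S and G2/M genes (median -0.31, 0.0285) were lower. The estimated p was 0.744 for S and G2/M genes and 0.647 for the others. In all 9 lists the difference was larger in replicate 1, as in AP-1 genes (10.38 and 9.41 against 9.53 and 9.31) and stress genes (10.75 and 9.86 against 10.05 and 9.64). Replicate 2 went the other way in squamous genes (3.72 and 4.27 against 6.69 and 4.00), S and G2/M genes (10.89 and 11.71 against 11.57 and 11.58) and TGF-beta response genes (9.61 against 9.84 in replicate 2). Inflammatory and unfolded protein genes passed only in the blocked fit (0.0760, blocked 0.0355; 0.134, blocked 0.0286). In EPCAM- cells EMT transcription factors were lower (2 of 16 positive, 3 fell alone, median -0.34, 1.7e-06, estimated p 0.403), a list that includes Nfatc1 and Creb3l1. S and G2/M genes were lower (median -0.26, 0.000233, estimated p 0.974), though not in replicate 2 (10.80 and 11.53 against 11.36 and 11.47). Cholesterol genes (24 of 24 positive; median 0.37, 1.7e-06, estimated p 0.901), simple keratins (1 of 4 rose alone, median 0.48, 0.000417, estimated p 0.403) and junction genes (3 of 36 rose and 1 fell alone, median 0.26, 0.0149, estimated p 0.901) were higher.

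In the Creb3l1 knockout Trim44, a TRIM family gene, had the smallest adjusted p in both fractions. It fell from 726 and 842 to 3 and 0 in EPCAM+ cells (log2 -8.61, standard error 0.57, adjusted p 1.88e-06) and at least 114-fold in EPCAM- cells (0 and 0 against 736 and 991, log2 -9.74, adjusted p 3.08e-07). The ceramide synthase Cers6 fell 159-fold in EPCAM+ cells (8 and 5 against 974 and 1097, lost with voom at 0.697), and the syndecan Sdc2 fell at least 8.77-fold in EPCAM+ cells and from 183 and 195 to 0 and 0 in EPCAM- cells. Krt17 fell 26.6-fold in EPCAM+ cells (210 and 85 against 4365 and 3481), as it did in the Pitx1 knockout. Prrx1, an EMT transcription factor, fell 1.95-fold in EPCAM- cells (2301 and 2219 against 4150 and 4650, log2 -0.96, adjusted p 0.0304). Trim44, Cers6 and Creb3l1 all lie on chromosome 2. Trim44 and Creb3l1 lie in the segment from 84 Mb that was shifted in the Pitx1 knockout. In the Creb3l1 knockout its median log2 fold change was -0.08 in EPCAM+ and -0.06 in EPCAM- cells. It held 1 of 36 falls (0.241 expected) and 2 of 47 (0.315 expected).

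In EPCAM+ cells 38 genes were called in the Creb3l1 knockout, 2 rose and 36 fell (blocked 69, 8 and 61). Hipk2 (2.72-fold) and Akap9 (2.61-fold) rose. Lrig3 (at least 17.9-fold), Epdr1 (at least 12.8-fold), Nipal4 (at least 9.14-fold), Gata4 (at least 8.77-fold), Cldn3 (3 and 0 against 58 and 331) and Zfp503 (3 and 0 against 58 and 76) fell. The count was 7 with only the compared groups and 15 with voom, 33 (11 rose and 22 fell) without control replicate 2, and 19 without knockout replicate 2; Cers6, Epdr1, Gata4, Sdc2 and Trim44, of 12 named calls, held with each library left out. Cldn3 (0.594), Hipk2 (0.0661), Lrig3 (0.513), Nipal4 (0.148), Sdc2 (0.0562) and Zfp503 (0.230) were lost with voom. In EPCAM- cells 51 genes were called, 4 rose and 47 fell (blocked 85, 9 and 76). Add2 (2.53-fold) and Akap9 (2.26-fold) rose. Sostdc1 (at least 124-fold, 0 and 0 against 1801 and 67), Cdh11 (at least 46.2-fold), Gpc4 (at least 45.8-fold), Lrch2 (at least 39.0-fold), Lrig3 (at least 35.8-fold), Cldn3 (at least 23.9-fold), Ptprz1 (3 and 0 against 169 and 159) and Epdr1 (0 and 3 against 183 and 138) fell. Of these, Sostdc1, Cdh11, Gpc4, Lrch2, Cldn3 and Ptprz1 were lower by more than 2 log2 units in all 4 knockouts. The count was 33 with only the compared groups, 26 without control replicate 1 and 74 (34 rose and 40 fell) without control replicate 2; Cldn3, Epdr1, Lrig3, Sdc2 and Trim44, of 13 named calls, held with each library left out. Cldn3 (0.425), Gpc4 (0.291), Lrch2 (0.465), Lrig3 (0.150) and Sostdc1 (0.778) were lost with voom.

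All list calls of the Creb3l1 knockout were lost with the estimated correlation. In EPCAM+ cells ribosomal protein genes (0 of 42 called, median -0.25, 1.6e-08, estimated p 0.931) and squamous genes (0 of 19 called, median -1.52, 0.00842, estimated p 0.931) were lower. The squamous difference came from control replicate 1 (3.77 and 4.13 against 6.69 and 4.00), and replicate 2 was higher in the knockout. In EPCAM- cells EMT transcription factors were lower (Prrx1 alone of 16 fell, 3 over the list alone, median -0.37, 0.00919, estimated p 0.837). Cholesterol genes were higher (0 of 24 called, 1 rose alone, median 0.20, 0.00919, estimated p 0.837), though not in replicate 2 (9.85 and 9.44 against 9.24 and 9.51).

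The Pitx1 and Creb3l1 knockouts lost some of the same genes. In EPCAM+ cells 9 genes fell in both, of 54 and 36 (0.0993 expected if independent): Krt17, Nrp1, Cldn3, Lrig3, Epdr1, Gata4, Emb, Tbx3 and Prkaa2. In EPCAM- cells 19 fell in both, of 113 and 47 (0.271 expected). Sharing was not limited to this pair. In EPCAM- cells Pitx1 and Klf5 shared 4 falls (0.156 expected), and Klf5 and Creb3l1 shared 2 (0.0649 expected). In EPCAM+ cells each of these 2 pairs shared 1 fall (0.0276 and 0.0184 expected). All knockouts are measured in a fraction against the same 2 control libraries, so part of each excess can come from the controls. The median log2 fold change of the 9 genes was -5.03 in Pitx1 and -4.86 in Creb3l1, against -0.08 in Klf5 and -0.72 in Nfatc1. Over the 19 genes in EPCAM- cells it was -5.46 and -5.22, against -1.69 in Klf5 and -1.41 in Nfatc1. Of the 19, Sostdc1, Cdh11, Gpc4, Lrch2, Cldn3 and Ptprz1 were lower by more than 2 log2 units in all 4 knockouts.

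**Figure D4:**
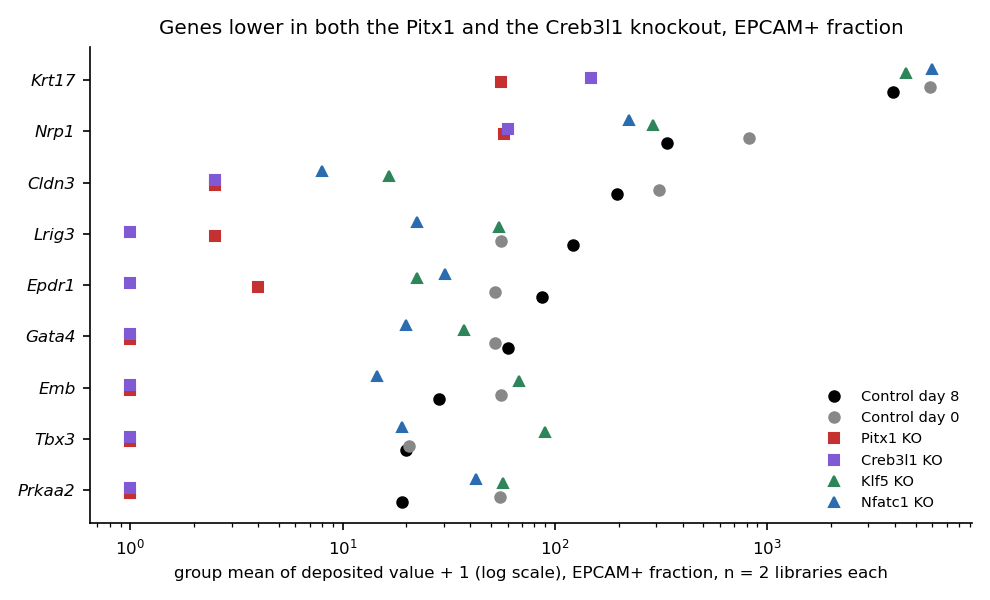
Group means plus 1 on a log axis in EPCAM+ cells (n = 2 libraries per group) for the 9 genes that fell in both the Pitx1 and the Creb3l1 knockout. Control day 8 is black and day 0 grey; squares are Pitx1 (red) and Creb3l1 (purple), triangles Klf5 (green) and Nfatc1 (blue).

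Across all tested genes, the fold changes of any 2 knockouts in the same fraction correlated at 0.416 to 0.615. Unchanged groups that share their control libraries gave 0.50 on average and 0.517 at most in 100 simulations. Each gene was simulated on its own, whereas genes of a library can move together. Neither these correlations nor the simulated covariance therefore bound what unchanged libraries would give. The covariance exceeded the simulated mean by 0.024 (Nfatc1 and Creb3l1, EPCAM+) to 0.135 (Klf5 and Nfatc1, EPCAM+). The fractions of 1 knockout share no library, and there Pitx1 had 37 shared falls (0.312 expected) and 14 shared rises, Klf5 9 shared falls (0.0138 expected), and Creb3l1 26 shared falls (0.0865 expected) and 1 shared rise. The fractions carry the same replicate numbers, and replicate differences correlated at 0.171 to 0.381 between the fractions of a line, so the counts expected if independent are not those of unchanged groups.

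Markers of other cell types were summed in each library. The summed values of immune markers were 293 to 645 per library (8 of 26 markers tested), of endothelial markers 487 to 1258 (6 of 16) and of melanocyte markers 63 to 602 (2 of 10). Dermal fibroblast markers summed to 12565 to 32071 (9 of 18), or 0.063 to 0.160% of a library, mostly Gsn and Ly6a, which tumour cells can express. The endothelial sum was 852 to 1258 in the 4 Pitx1 knockout libraries against 487 to 630 in the 4 day 8 control libraries. It was also above these in the 4 Creb3l1 libraries (653 to 911) and in replicate 1 of Klf5 (799 and 790). In Pitx1 Flt1 led it (902, 598, 550 and 497 against 134, 201, 171 and 179), and was not called (adjusted p 0.0512 in EPCAM+ and 0.137 in EPCAM-). Of these lists only the fibroblast markers were called once, lower in EPCAM- cells of the Klf5 knockout (0 of 9 called, 7 negative; 0.0364, estimated p 0.372).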

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

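The copy number test and the EPCAM+ test of the shared genes below were chosen after the values had been seen; the other tests were written beforehand. The bootstrap bound and the smallest number of silent genes were also settled afterwards.

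In the Pitx1 knockout whole chromosomes were shifted, with medians of 0.31 and 0.36 on chromosome 12 and -0.30 and -0.34 on chromosome 13. A bias by GC content and gene length was tested by taking out a smooth trend. The smallest of the 6 medians was then 0.178 (0.199 before), below the bound of 0.2 set beforehand, so by that bound the test is undecided. Its bootstrap lower bound of 0.143 was still above the 0.1 that a bias would leave. That bootstrap drew the genes of a chromosome again, so it measures the spread over genes and not between libraries. A deviation of the day 8 control libraries was tested against the day 0 control, where the EPCAM+ medians kept at least 0.86 of their size. DNA copy number stays open. All 4 library pairs moved the same way on all 4 segments, but the segments were picked from these same libraries, so that outcome was close to fixed. Elsewhere the 4 pairs also shared a sign: on chromosome 13 in the Klf5 knockout (-0.17, -0.05, -0.17 and -0.05) and on chromosome 19 in the Creb3l1 knockout (0.08, 0.27, 0.22 and 0.32). On the chromosome 2 segment they did so in all 3 other knockouts: Klf5 (0.07, 0.06, 0.13 and 0.07), Nfatc1 (0.16, 0.07, 0.20 and 0.05) and Creb3l1 (-0.09, -0.08, -0.03 and -0.14). DNA was not measured here, so the shift of genes on those segments cannot be assigned to the loss of Pitx1.

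Genes low in both the Pitx1 and the Creb3l1 knockout could come from control libraries that happened to be high. In EPCAM+ cells the day 0 control, which is other libraries, gave medians of at least 1.11 times those against day 8 (Pitx1 -5.57 against -5.03, Creb3l1 -5.67 against -4.86), so a high day 8 control does not explain them. In EPCAM- cells there is no other control, and the Klf5 knockout, which shares it, had 0.31 of the Pitx1 median, between the bounds set beforehand, and that case stays open. Reads shared between near-identical copies stay open: 0 of the 19 shared genes lay within 1 Mb of another, but a copy need not be one of the 19 or lie nearby, and Krt17 among them has close paralogs.

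Some genes were silent in a knockout (at most 3 reads in its 4 libraries together) and at 50 or more in all 4 day 8 control libraries: Crmp1 and Cldn3 in Pitx1, and Epdr1, Trim44 and Cldn3 in Creb3l1. At least 207 reads were expected at the control level. Choosing genes at 50 or more in the control libraries made a high expected number close to fixed. The 4 libraries of either knockout together held more reads in genes than the 4 control libraries. Lower depth therefore does not explain the silent genes. A narrower mixture of cells in the knockout lines was also tested, and 0 genes were silent the other way. With 0 silent genes in Klf5 and Nfatc1 the ratio was 0 there, and fewer than 5 silent genes per knockout is too small a number for that test, so it stays open.

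The interactions called no gene, yet 18 gene lists were called in them at the preset correlation, and all 18 were lost with the estimated correlation. In the Pitx1 knockout they were junction genes (adjusted p 0.0266, median 0.39), simple keratins (0.00846, 0.71), EMT transcription factors (0.00177, -0.40), inflammatory genes (0.0139, 0.32), hypoxia genes (0.0478, 0.13), ribosomal protein genes (0.00644, 0.13) and mitochondrially encoded genes (0.0266, -0.29), with estimated p 0.436 to 0.836. In Klf5 they were junction genes (0.00897, 0.21), squamous genes (0.00233, 1.45), simple keratins (0.00233, 0.38) and EMT transcription factors (0.00629, -0.40), with estimated p 0.807. In Nfatc1 they were EMT transcription factors (0.0199, -0.26), TGF-beta response genes (0.0348, -0.22) and ribosomal protein genes (2.10e-11, 0.30), with estimated p 0.809. In Creb3l1 they were junction genes (0.00185, 0.24), simple keratins (0.0426, 0.36, blocked 0.0625), EMT transcription factors (5.94e-05, -0.46) and ribosomal protein genes (4.11e-05, 0.16), with estimated p 0.907; matrix genes passed only in the blocked fit (0.0525, blocked 0.0136). For the EMT transcription factor list this means a smaller difference between EPCAM- and EPCAM+ cells than in the control line, which is shared by all 4 tests. The list also contains Nfatc1 and Creb3l1.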

How the results depend on the processing

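Counts of called genes moved by more than 1.5-fold in many settings, and 0 calls of a named gene reversed in any. The cause of these moves was not tested.

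With the replicate number as a block, more genes were called in all but the interactions. The control line had 2 genes between the days, 224 between the fractions and 843 for EPCAM- at day 8 against day 0. Against the control, Pitx1 had 386 and 491 genes in EPCAM+ and EPCAM- cells, Klf5 27 and 59, Nfatc1 1 and 1, and Creb3l1 69 and 85. Between fractions there were 138 in Pitx1, 102 in Klf5, 187 in Nfatc1 and 114 in Creb3l1. The block ended 5 of 236 named calls and gained 2, which were Nfatc1 in its own knockout (log2 -1.74, adjusted p 0.00065 and 0.000644).

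With only the compared groups in the fit, which leaves few degrees of freedom, counts fell to 14 between the control fractions, 161 for EPCAM- at day 8 against day 0, 2 and 11 for Pitx1, 0 and 0 for Klf5, 7 and 33 for Creb3l1 and 8, 0, 0 and 23 between fractions in Pitx1, Klf5, Nfatc1 and Creb3l1. Nfatc1 in EPCAM- cells had 1. Pitx1 in its own EPCAM+ knockout kept log2 -1.65 but at adjusted p 0.130, and 178 of 236 named calls were lost.

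Without the filter on low values the counts were 2 between the control days, 61 for Klf5 and 4 for Nfatc1 in EPCAM- cells, 66 and 79 for Creb3l1, and 86 between fractions in each of Klf5 and Creb3l1. A pseudocount of 0.5 gave 7 genes between the control days. A pseudocount of 5 gave 1 gene for Nfatc1 in EPCAM+ cells and called Creb3l1 in its own EPCAM- knockout (log2 -3.16, adjusted p 0.0263). Creb3l1 was no lower there than in EPCAM- cells of the Nfatc1 knockout (6 and 0 against 0 and 0). A voom fit on the recovered reads, added later, gave 39 for Pitx1 and 5 for Klf5 in EPCAM+ cells, 11 for Klf5 in EPCAM- cells and 15 for Creb3l1 in EPCAM+ cells, and lost 91 named calls. Leaving out the shifted chromosome segments, also added later, gave 52 and 103 for Pitx1. TMM and upper-quartile scaling moved no count that far, and shifted the all-gene median by less than 0.1.

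With each library left out in turn, counts were 0 to 3 between the control days, 32 to 177 between the control fractions and 98 to 304 for EPCAM- at day 8 against day 0. They were 23 to 80 and 28 to 182 for Pitx1, 1 to 46 and 6 to 73 for Klf5, 0 to 3 and 0 to 10 for Nfatc1, and 19 to 33 and 26 to 74 for Creb3l1. Between fractions they were 19 to 56 in Pitx1, 5 to 38 in Klf5, 16 to 52 in Nfatc1 and 6 to 29 in Creb3l1, and 0 in all interactions. For the targeted genes in their own knockouts, log2 was -1.81 to -1.49 and -2.32 to -1.93 for Pitx1, -0.30 to 0.28 and -0.49 to 0.22 for Klf5, -2.11 to -1.37 and -2.17 to -1.32 for Nfatc1, and 0 to 2.00 and -5.93 to -3.12 for Creb3l1. At least 1 left-out library ended 173 of 236 named calls, and 23 calls held in every setting.

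Of 551 list tests 133 were called; with the estimated correlation 14 remained, with the block 140 (3 lost, 10 gained) and with TMM 126 (10 lost, 3 gained), and 0 reversed. The 14 were the junction and regulator lists in the 6 comparisons of EPCAM- with EPCAM+ cells and simple keratins in the control line. The planned edgeR and DESeq2 fits were not run, as the deposited values were scaled. The voom fit on recovered reads stands in their place.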

Other observations

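Genes that departed from the control line by more than 2 log2 units in all 4 knockouts were sought in day 8 EPCAM- cells. They were picked after looking at the values. With both control libraries at 50 or more, 13 genes were lower. With every knockout EPCAM- library at 50 or more, 3 genes were higher. The bound of 50 left out Creb3l1 (control 137 and 26). Control values (replicate 1 and 2) were 1801 and 67 for Sostdc1, 1271 and 216 for Id4, 357 and 340 for Cdh11, 152 and 539 for Gpc4, 157 and 432 for Lrch2, 234 and 301 for Gli2, 399 and 133 for Zfhx4, 157 and 214 for Gpr149, 69 and 292 for Cldn3, 200 and 186 for Hdgfrp3, 169 and 159 for Ptprz1, 180 and 131 for Thsd7a and 123 and 136 for Cxxc4. No knockout EPCAM- library was above 3 for Sostdc1, 47 for Cdh11 or 29 for Gpc4. The higher genes were Sema4f (control 3 and 76), Lce1g (0 and 143) and Cldn4 (95 and 1069). A gene that departs in all 4 knockouts can reflect the shared control libraries, and the spread between the 2 control values was wide for several.

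Klra genes, natural killer receptors by name, were found in EPCAM+ tumour cells. Klra8 averaged 167 over the 12 EPCAM+ libraries (12 to 342) and 3.9 over the 10 EPCAM- libraries (11 at most), and Klra9 91.3 and 2.3. Klra2 (15.7 and 17.7) and Klra6 (3.3 and 3.8) were near the same level in both fractions. The leukocyte genes Ptprc (1.2), Nkg7 (0.5), Gzma (0), Gzmb (0.3), Prf1 (0.2), Ncr1 (0) and Klrb1c (0.8) were near 0 on average over the EPCAM+ libraries, while Il2rb was at 3.8 and Coro1a at 20.4 (6.6 and 27.9 in EPCAM- libraries). The Klra genes are close paralogs, and the source copy is uncertain.

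The comparison of fractions within each knockout called further lists, all lost with the estimated correlation. Basal keratinocyte genes were lower in Pitx1, Klf5, Nfatc1 and Creb3l1 (5.8e-07, 8.8e-07, 4.3e-05 and 1.18e-06; estimated p 0.106, 0.114, 0.203 and 0.0906). Simple keratins were lower (0.00161, 0.000355, 1.56e-05 and 1.97e-06; estimated p 0.274, 0.179, 0.126 and 0.0801), and cholesterol genes too (0.00202, 1.95e-06, 5.7e-07 and 7.4e-06; estimated p 0.549, 0.387, 0.410 and 0.562). EMT transcription factors were higher with 0 called in each (0.0437, 0.000624, 0.00917 and 0.0419; estimated p 0.530, 0.292, 0.430 and 0.594). Squamous genes, with Lypd3 as the called member, were lower in Pitx1, Nfatc1 and Creb3l1 (0.0141, 0.000631 and 0.00942; estimated p 0.526, 0.410 and 0.594).

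Calls in single knockouts were also found between fractions. Surface markers of EMT states, with Epcam as the called member, were lower in Pitx1, Klf5 and Nfatc1 (0.0249, 0.0487 and 0.00917, with estimated p 0.328, 0.387 and 0.347). Epcam is the marker the cells were sorted on, so its fall was fixed by the sort. These list calls follow from it in part. Ribosomal protein genes were higher in Nfatc1 (42 of 42 positive, 1.13e-06, estimated p 0.486) and Creb3l1 (0.0102, estimated p 0.833), and S and G2/M genes lower (0.00363 and 0.0164; estimated p 0.741 and 0.833). In Pitx1, mitochondrially encoded genes were lower (0.00014, estimated p 0.278). Matrix proteases (0.0191, estimated p 0.522), YAP-TEAD targets (0.0437, blocked 0.0591, estimated p 0.549) and inflammatory genes (Csf1 called; 0.0491, blocked 0.0654, estimated p 0.449) were higher there. Interferon genes were higher in Klf5 (0.0272, estimated p 0.442). Only in the blocked fit were matrix proteases called in Klf5 (0.0942, blocked 0.0304) and interferon (0.0992, blocked 0.0356) and inflammatory genes (0.0575, blocked 0.0374) in Creb3l1.

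Lists that were never called outside the interactions had smallest adjusted p of 0.0830 for calcineurin and NFAT genes, 0.0738 for unfolded protein genes, 0.0807 for hypoxia genes, 0.0716 for secretory pathway genes, 0.184 for immune, 0.359 for endothelial and 0.111 for melanocyte markers.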
